A study of Mus musculus with 7 samples.

How the data were processed

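RNA from the olfactory epithelium of mice at postnatal day 7 was sequenced in 7 libraries, 1 from an Amigo1+/+ animal (WT), 3 from Amigo1-/- animals (KO) and 3 from Amigo1neo/neo animals (neo). Per the labels' protocols, total RNA was extracted with RNeasy columns and libraries were made with the KAPA RNA Hyperprep kit after poly(A) capture. Groups and replicate numbers were taken from the sample titles. The sample names carry a date-like number and a code that WT and KO share and that differ in neo. The labels explain neither, and they are read here as date and line name. Date, line and the neo genotype cannot be told apart, and no batch term could be fitted.

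The authors deposited whole-number read counts per gene, made with Trimmomatic 0.35 and STAR 2.5.1b on GRCm38 (mm10), per the submitters' processing notes, and the name of the table says that counting was stranded. The role of each of those tools is not given in the sources used here. The authors' count table held 50600 genes and 4 summary rows that name no gene, which were left out of library sizes and tests. Of all reads, 14.5 to 19.6% were in the multimapping row, 14.2 to 17.4% matched no feature, 0.666 to 0.865% were ambiguous and 3.32 to 4.38% were unmapped. Multimapping reads were therefore absent from the gene rows, and near-identical genes, such as some olfactory receptor genes and pseudogenes, can be undercounted. The deposited TPM values per gene and per transcript were RSEM estimates scaled to the same sum in every library, per the file headers and the column sums. The authors' deposited comparison gave log2 fold changes of KO against neo made with DESeq2 1.18.1, per the file headers and the submitters' processing notes. Recomputing its group means from the columns of the same table gave the 3 KO libraries on one side and the 3 neo libraries on the other. The authors also deposited the p-values and adjusted p-values of that comparison, and a standard error per fold change used here as a score, per the file headers. The same deposited table held a normalised signal per gene and library, which is the gene count divided by 1 factor per library, per the file headers and its constant ratio to the counts. FPKM tables were not used here.

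Total gene counts were 21343058 in WT, 17008840, 18565342 and 18697771 in KO replicates 1 to 3, and 21063122, 17983184 and 14879415 in neo replicates 1 to 3. The gene Gm42418, which overlaps ribosomal RNA sequence, took 9.83 to 16.5% of gene counts. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 9.58), so each was counted as 1 sample. Of the gene identifiers, 45737 matched GENCODE vM21, all with the same coordinates, and coordinates are given on GRCm38. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples, which may in part be technical.

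Gene counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM normalisation, filterByExpr (minimum count 10, minimum total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05, two-sided. The comparison of neo with KO used those 6 libraries. Comparisons with WT used all 7, with the WT library assumed to vary like the others, since it has no replicate. Standard errors came from the quasi-likelihood F statistic. Levels are CPM (counts scaled by library size) after TMM over the 7 libraries. Ratios of pooled counts have exact 95% intervals, which cover counting error only. For 37 gene lists, camera from limma 3.58.1 used a preset correlation of 0.01, and an estimated correlation and fry were alternatives. Calls within 500 kb of Amigo1 were compared with calls elsewhere by Fisher's exact test. Transcripts were tested with limma on log2(TPM + 0.1) at a mean TPM of at least 0.5. The share of counts in olfactory receptor genes was compared by an exact permutation test, whose smallest p with 3 libraries against 3 is 0.1. Class I receptor genes were taken as those in a fixed window of the chromosome 7 cluster, and all other Olfr genes as class II.

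The gene lists, tests and alternatives were chosen before the data were examined. So was the rule for naming genes: per comparison, up to 12 genes higher and 12 lower past the threshold with no overlap between groups and with no clone-type symbol or pseudogene suffix, then the Amigo family, called neighbours within 500 kb and the nearest gene on each side, up to 4 called members per list or otherwise up to 2 with the smallest p, and up to 5 receptor genes in each direction. Genes named outside that rule are marked as chosen after their values were seen. Alternatives were RLE size factors, TMM without chemosensory receptor genes, no count filter, a filter of 50 counts in 3 libraries, all 7 libraries in 1 fit, only the groups compared, a replicate block, leaving out each library, DESeq2 1.42.0, limma on gene TPM with pseudocounts of 0.1 and 1, a test against a fold of 1.2, distances of 100 kb and 1000 kb, other denominators for the receptor share, and another pseudocount or a mean TPM minimum of 0.1 for transcripts. A spread without robust weighting and a receptor share without Gm42418 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

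The steps were tested on simulated counts drawn from the 6 neo and KO libraries, with 50 genes changed at each fold. edgeR recovered 9 at 1.5-fold, 32 at 2-fold, 42 at 4-fold and 45 at 8-fold, among 17420 genes tested. Its calls also held 18 unchanged genes, 12.3% of all calls and above the nominal rate. DESeq2 recovered 14, 35, 43 and 46 and called 44 unchanged genes (24.2%), and limma recovered 5, 31, 42 and 45 and called 19 unchanged genes (13.4%). With no gene changed, edgeR called 1 gene. Of 37 lists, both shifted lists were called, and 1 unshifted list. Simulated genes were drawn independently of one another, so this cannot show how often camera calls unshifted lists whose members vary together.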

Results

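The olfactory epithelium, the sensory lining of the nose, was profiled by RNA sequencing in 7 mouse libraries at postnatal day 7, with 1 WT, 3 KO and 3 neo libraries. In neo animals a neomycin selection cassette stands in place of the Amigo1 coding region. Amigo1 encodes a leucine-rich repeat cell adhesion protein that associates with Kv2 potassium channels. The series asked whether the cassette itself alters expression in this tissue. Gene counts totalled 14879415 to 21343058 per library.

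Amigo1 (ENSMUSG00000050947.9, GRCm38 chromosome 3, 108186335 to 108192286, plus strand) had 744 counts in WT. It had 0, 8 and 16 counts in KO replicates 1 to 3, where the 0 allows up to 3 counts, and 11, 5 and 1 counts in neo replicates 1 to 3. Pooled counts were 75.7-fold lower in KO than in WT (95% counting interval 50.5 to 119) and 111-fold lower in neo (69.0 to 192). The fitted changes from WT were -6.24 in KO (log2, SE 0.86, adjusted p = 1, edgeR) and -6.81 in neo (adjusted p = 0.609, edgeR), so neither passed across all genes. Without KO replicate 1, Amigo1 passed in the comparison of neo with WT (adjusted p = 0.0170, edgeR). Amigo1 was below the count filter in the comparison of neo with KO.

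KO was compared with WT to ask what loss of Amigo1 changes. Gpr61, an orphan G protein-coupled receptor gene 31.5 kb from Amigo1 (chromosome 3, 108148321 to 108154882, minus strand), had 1 count in WT, or 0.0460 CPM. It stood at 27.6 ± 0.504 CPM in KO (SD, n = 3), a pooled ratio of 599 (95% counting interval 107 to 23690). Gpr61 rose by 9.03 on the log2 scale (SE 0.39, adjusted p = 5.3e-05, edgeR), higher in 3 of 3 KO libraries. Cyb561d1 and Atxn7l2, the neighbours on the other side of Amigo1, differed by -0.26 and -0.20 from WT (adjusted p = 1 for both, edgeR). At an unadjusted p under 0.05 there were 139 of 19123 genes tested, where 956 are given by chance. So few small p-values mean that this test, with 1 WT library, can miss changes, as it did for Amigo1. Gpr61 was the only call by edgeR. The count was 4 without neo replicate 1, when the Y-linked genes Ddx3y, Kdm5d and Uty joined Gpr61, 2 without neo replicate 3, when Vip joined it, and 6 in a fit of WT and KO alone. In that fit Vip and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty joined Gpr61. The WT library had 644 CPM of Xist, the transcript of the inactive X chromosome, and 0.0460 CPM of Ddx3y. KO libraries had at most 4.18 CPM of Xist and at least 60.7 CPM of Ddx3y. By these transcripts WT was female and every KO library male, so sex and loss of Amigo1 cannot be told apart in this comparison. Outside it, neo replicate 1, also high in Xist (1145 CPM) and with 0 CPM of Ddx3y, had 28.9 CPM of Gpr61. High Gpr61 was therefore not limited to male libraries, though neo replicate 1 is 1 library of another genotype.

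The comparison of neo with WT asked what the cassette allele as a whole changes. Gpr61 stood at 25.7 ± 2.92 CPM in neo (SD, n = 3) and rose by 8.93 on the log2 scale against WT (adjusted p = 5.8e-05, edgeR), a pooled ratio of 568 (95% counting interval 101.7 to 22430). Cyb561d1, a cytochrome b561 family gene 3.4 kb from Amigo1 (chromosome 3, 108195687 to 108201212, minus strand), stood at 21.7 CPM in WT and 2.23 ± 0.621 CPM in neo. It fell by 3.30 on the log2 scale (SE 0.25, adjusted p = 0.00364, edgeR), lower in 3 of 3 neo libraries. At an unadjusted p under 0.05 there were 567 of 19123 genes tested, where 956 are given by chance, so this test too can miss changes. Gpr61 and Cyb561d1 were the 2 calls. In a fit of WT and neo alone the Cyb561d1 call was lost (adjusted p = 0.182, edgeR), and the count was 5 without KO replicate 1 and 6 without neo replicate 1. Those 6 held the Y-linked genes Ddx3y, Kdm5d and Uty. By Xist and Ddx3y, WT and neo replicate 1 were female and neo replicates 2 and 3 male, so these fits without neo replicate 1 also compare sexes. Gpr61 was called in both comparisons, which share the WT library. In 20 simulations all 7 libraries, WT included, were redrawn with no difference between groups. On average 1.05 genes were called in both comparisons, 2.1 in the neo and 2.95 in the KO comparison. The numbers of calls here are no larger than that. The simulations counted calls only, so they do not speak to the size of the Gpr61 difference. Independent lists would share 5.2e-05 genes higher than WT, and the WT library cannot be split.

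Neo was compared with KO to separate the cassette from the loss of Amigo1. Cyb561d1 was 18.1 ± 0.901 CPM in KO and 2.23 ± 0.621 CPM in neo (SD, n = 3 each) and fell by 3.04 on the log2 scale (SE 0.21, adjusted p = 0.00348, edgeR). Olfr287 (chromosome 15, 98206971 to 98221056), an olfactory receptor gene, fell from 2.24 ± 0.404 to 0.167 ± 0.0629 CPM (log2 change -3.72, SE 0.39, adjusted p = 0.0360, edgeR). Gm5841 (chromosome 3, 8327531 to 8329707), far from Amigo1 on the same chromosome and named after its values were seen, rose from 0.0930 ± 0.0275 to 2.66 ± 0.992 CPM (log2 change 4.71, adjusted p = 0.0360, edgeR). Each of these 3 genes lay on the same side of every KO library in 3 of 3 neo libraries. Atxn7l2, an ataxin 7-like gene 9.9 kb from Amigo1 (chromosome 3, 108202222 to 108210934, minus strand), was 5.78 ± 1.45 CPM in KO and 1.31 ± 0.159 CPM in neo, a log2 difference of -2.13 that did not pass (adjusted p = 0.107, edgeR). Gpr61 differed by -0.10 (adjusted p = 0.843, edgeR), Amigo2 by -0.26 (adjusted p = 0.852) and Amigo3 by -0.12 (adjusted p = 0.927).

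These 3 genes were the edgeR calls among 17638 tested, 1 higher and 2 lower in neo, while 1643 genes had an unadjusted p under 0.05 against 882 by chance. That number was 966 without neo replicate 3, 971 without KO replicate 2 and 2417 without neo replicate 1. Groups did not overlap for 2746 genes, where chance gives 10% of those tested. DESeq2 called 95 genes on the same counts, and the authors' deposited table held 79 genes at an adjusted p under 0.05, of which 53 were higher in KO and 26 in neo. All 3 genes called by edgeR were among the authors' 79. Cyb561d1 stayed past the threshold in all 15 alternatives run for it. Olfr287 and Gm5841 lost their calls when any library other than neo replicate 1 was left out (adjusted p up to 0.388, and 3.5e-05 and 2.5e-06 at the lowest over their alternatives), and the count ranged from 1, without KO replicate 2, KO replicate 3 or neo replicate 3, to 17 without neo replicate 1.

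Around Amigo1, 30 genes within 500 kb were tested and Cyb561d1 was the only edgeR call, against 2 calls among 17608 genes elsewhere (Fisher's exact test, two-sided, p = 0.00509). Adjusted over the list alone, 2 of the 30 fell and 2 rose. The lower genes were the adjacent Cyb561d1 and Atxn7l2. The higher genes were Psma5, a proteasome subunit gene 64.6 kb away with 36.8 ± 3.81 CPM in KO and 53.3 ± 3.87 CPM in neo, and Gm42754, 34.5 kb away, with 1 count in KO and 56 in neo (ratio 53.8, 95% counting interval 9.27 to 2163). Both were named after their values were seen and missed the threshold over all genes (adjusted p = 0.340 and 0.134, edgeR). Counting was stranded per the name of the table, and Gm42754 lies on the plus strand while Cyb561d1 and Atxn7l2 lie on the minus strand. No transcript of these neighbours passed limma on TPM, with 86 tested. Nor did any of the 44981 transcripts tested in all, so this lack of calls says little about the neighbours. At an unadjusted p under 0.05 there were 5 neighbouring transcripts. Those of Cyb561d1 (-3.07) and Atxn7l2 (-3.18) were lower in neo, and those of Psma5 (0.63), Gm42754 (3.75) and Gstm7 (0.36) were higher. DESeq2 called 4 genes in this interval, as did the authors' deposited table.

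**Figure D1:**
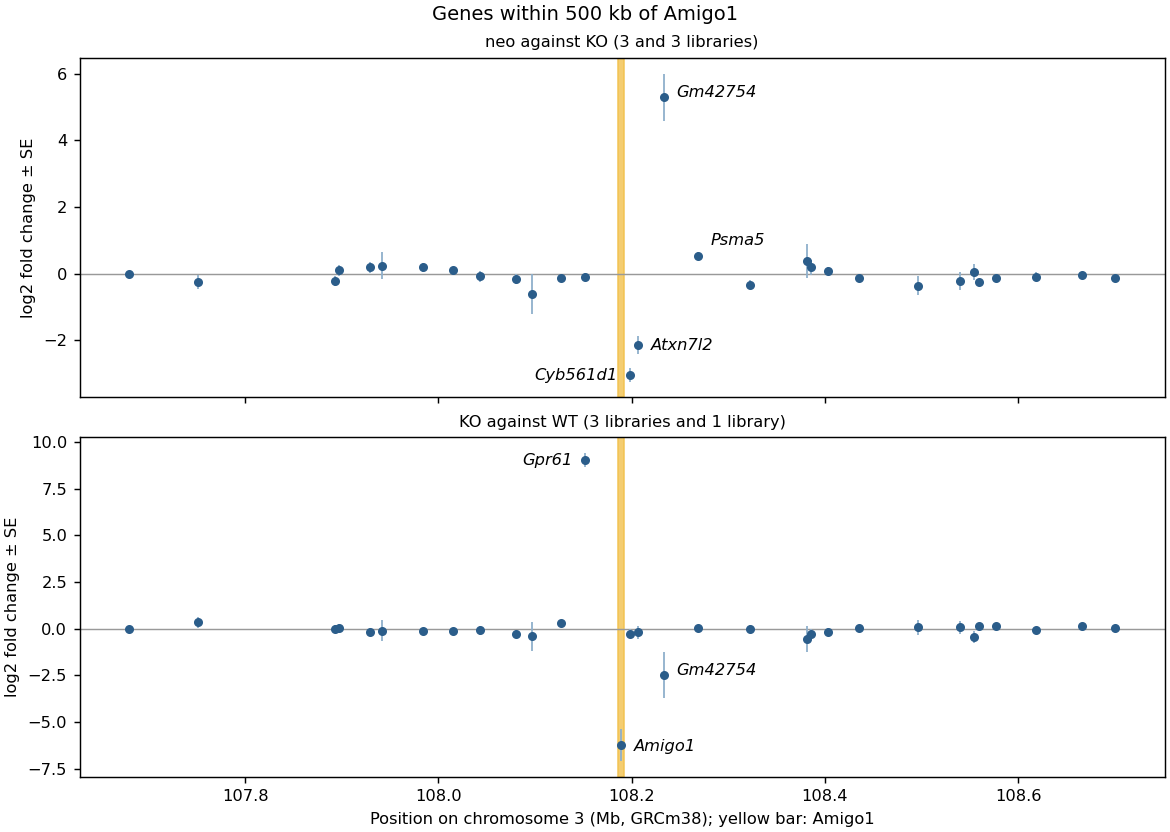
Log2 fold changes with standard errors for genes within 500 kb of Amigo1 that were tested between neo and KO, and in the bottom panel Amigo1 itself (yellow bar), plotted by position on chromosome 3 in Mb, for neo against KO (top, 3 and 3 libraries) and KO against WT (bottom, 3 libraries and 1 library). Cyb561d1 lies at -3.04 in the top panel and Gpr61 at 9.03 in the bottom panel.

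Olfactory receptor genes mark the receptor that each sensory neuron expresses. In neo against KO, 758 of 1040 receptor genes tested had a positive fold and the median was 0.25 on the log2 scale. At an unadjusted p under 0.05, 135 were higher and 50 lower, where 26 each way are given by chance. The lower count was 25 without KO replicate 2, and 20 and 19 with limma on TPM at the pseudocounts of 0.1 and 1. On TPM the median fold over all genes was 0.097 and 0.087, against -0.002 in edgeR. Leaving out each library gave 100 receptor genes (without KO replicate 2) to 277 (without KO replicate 1) in both directions together, and medians of 0.16 to 0.37. Olfr287 was the only receptor gene past the threshold in edgeR, and DESeq2 called 12, of which 9 were lower in neo. The other lower receptor genes with the smallest p were Olfr1369-ps1 (-1.50), Olfr1508 (-1.61), Olfr1205 (-1.99) and Olfr1228 (-1.38). Olfr1508 stood at 22.8 ± 7.84 CPM in KO and 7.49 ± 1.71 CPM in neo. The higher ones were Olfr686 (1.07), Olfr1370 (0.63), Olfr1537 (0.83), Olfr301 (0.77) and Olfr1222 (0.67), and none of these 9 passed (adjusted p = 0.271 to 0.384, edgeR). Of 99 class I genes tested none passed in edgeR, with 4 higher and 0 lower at an unadjusted p under 0.05. Olfr686 lies at 105201858 on chromosome 7, outside the fixed window, and was counted as class II.

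Receptor genes together took 0.353 ± 0.0229% of gene counts in KO and 0.410 ± 0.0665% in neo (SD, n = 3 each), against 0.393% in WT (95% Wilson interval 0.391 to 0.396, counting error only). The difference was within the spread (exact permutation test, two-sided, p = 0.3, smallest possible p 0.1). Without Gm42418 in the total, an alternative added after the data were seen, all 3 neo shares lay above all 3 KO shares, at 0.471 ± 0.0583% against 0.404 ± 0.0208% (exact permutation p = 0.1). Per count of mature neuron markers the ratio of neo to KO was 0.994, on the other side of 1 from the ratio of 1.16 by gene counts (exact permutation p = 1). Without neo replicate 1, whose share was 0.483%, the ratio was 1.06.

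**Figure D2:**
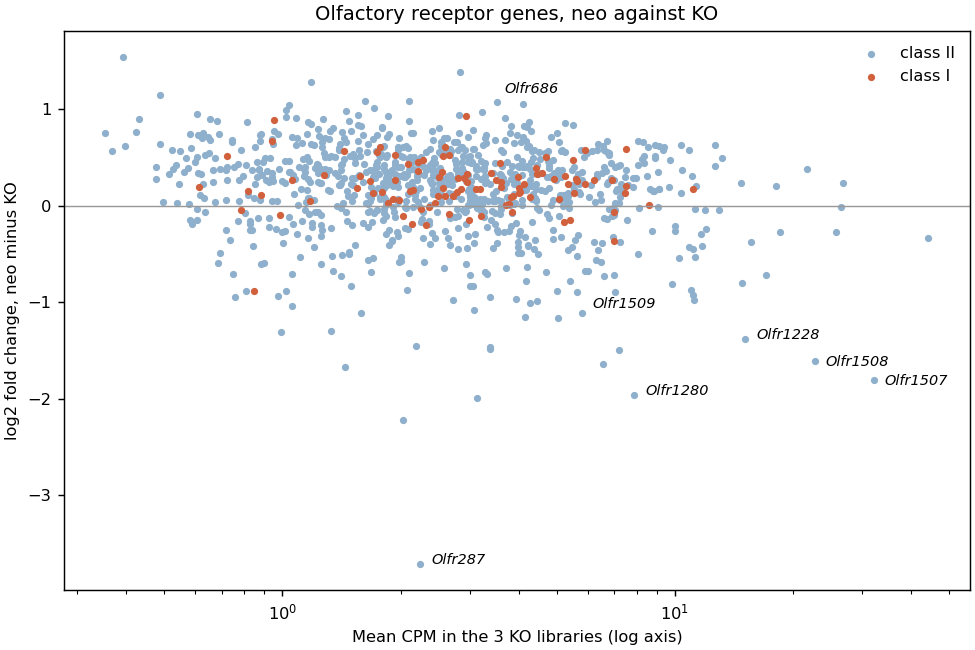
Log2 fold change of neo against KO for each olfactory receptor gene tested, against its mean CPM in the 3 KO libraries on a log axis, with class I genes in orange and class II genes in blue. The median fold is 0.25 and Olfr287 lies at -3.72, and the labels of Olfr1507, Olfr1509 and Olfr1280 were chosen after their values were seen.

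Gene lists for cell types and pathways were compared between neo and KO, and 13 of 37 passed camera with the preset correlation, 9 higher and 4 lower. All 13 calls were lost with a correlation estimated from the data (lowest adjusted p = 0.610, with 0 lists at an unadjusted p under 0.05), and fry for change in 1 direction called 0 lists (lowest adjusted p = 0.387, with 2 lists at an unadjusted p under 0.05). Without neo replicate 1, camera called 15 lists, 10 of them among the 13 and in the same direction. In edgeR no list member outside the receptor genes and the Amigo1 neighbourhood passed over all genes, while DESeq2 passed Col1a2, Col1a1, Bglap and the ribosomal protein gene Rps2, all lower in neo (adjusted p = 0.00137, 0.00345, 0.00504 and 0.00515).

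Mature olfactory neuron genes rose with a median of 0.17, with 19 of 19 positive (adjusted p = 5.4e-05, camera), among them Umodl1 at 0.44 and Ric8b, which chaperones the olfactory G protein, at 0.29. Proliferation genes rose with a median of 0.28, with 15 of 15 positive (adjusted p = 3.7e-06, camera), among them the topoisomerase gene Top2a at 0.35 and the replication licensing gene Mcm5 at 0.38. Adjusted over the list alone, no member of either list passed, and both lists had an adjusted p = 0.610 with an estimated correlation. Class II receptor genes rose with a median of 0.25 (adjusted p = 5.2e-06, camera, and adjusted p = 0.610 with an estimated correlation). Adjusted over the list alone, 1 class II gene, Olfr287, was lower and no class I gene passed. Class I genes rose with a median of 0.19 (adjusted p = 5.8e-05, camera, and adjusted p = 0.703 with an estimated correlation). Over all alternatives that median ran from 0.09 to 0.44. The class I call was lost without neo replicate 1, KO replicate 2 or KO replicate 3 (medians 0.14, 0.09 and 0.12, adjusted p = 0.0594, 0.158 and 0.0895, camera). Trace amine receptor genes rose with a median of 0.40, with 9 of 11 positive (adjusted p = 0.0102, camera), and dorsal epithelium genes with a median of 0.34, with 9 of 12 positive (adjusted p = 0.00896, camera), and these lists share Taar genes. Without KO replicate 2 both calls were lost (adjusted p = 0.151 and 0.136), and without KO replicate 3 the trace amine call was lost (adjusted p = 0.0674). Among them were Taar7a at 0.70, Taar6 at 0.50, and the dorsal zone enzyme genes Acsm4 at 0.48 and Nqo1 at 0.44. Both lists had an adjusted p = 0.610 with an estimated correlation, and no member of either passed adjusted over the list alone. By library, the class I median against the KO mean was 0.422 in KO replicate 1, above 0.345, 0.237 and 0.096 in neo replicates 1 to 3. KO replicate 1 also lay above neo replicate 3 for mature neuron (0.156 and 0.154) and dorsal genes (0.25 and 0.161). For class II genes it lay above neo replicate 2 (0.145 and 0.134). Proliferation and trace amine medians did not overlap between groups.

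Bone and cartilage genes fell with a median of -0.67 (adjusted p = 9.5e-06, camera), and adjusted over the list alone 5 of 12 were lower and 1 was higher. Bglap, which encodes osteocalcin, had a log2 change of -1.91, and Col9a1, a cartilage collagen gene, had 0.42. Fibroblast genes fell with a median of -0.22 (adjusted p = 0.00142, camera), and adjusted over the list alone the type I collagen genes Col1a1 (-1.09) and Col1a2 (-1.10) were lower. Sensory activity genes fell with a median of -0.42, with 9 of 10 negative (adjusted p = 0.00265, camera), among them the activity-regulated genes Arc at -0.56 and Nr4a1 at -0.60. The Amigo1 neighbourhood fell with a median of -0.10 (adjusted p = 0.0389, camera), and fry for change in either direction gave an adjusted p = 0.000149. All 4 lists had an adjusted p = 0.610 with an estimated correlation, and without neo replicate 1 the sensory activity and neighbourhood calls were lost (adjusted p = 0.0967 and 0.259). The sensory activity call was also lost without KO replicate 3, with a median of -0.02 (adjusted p = 0.211). The neighbourhood call was also lost without KO replicate 1, KO replicate 2 or neo replicate 3 (adjusted p = 0.0660, 0.0541 and 0.0742).

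Macrophage genes rose with a median of 0.47, with 7 of 10 positive (adjusted p = 0.00265, camera), among them Aif1 at 1.01 and Adgre1 at 0.78, while the lysosomal gene Cd68, chosen after its values were seen, had -0.72. Interferon response genes rose with a median of 0.44, with 11 of 13 positive (adjusted p = 0.00265, camera), among them Isg15 at 0.97 and Ifi44 at 0.67. Mitochondrial transcripts rose with a median of 0.30, with 7 of 7 positive (adjusted p = 0.00273, camera), among them mt-Nd2 at 0.33 and mt-Nd5 at 0.32. These 3 lists had an adjusted p = 0.610 with an estimated correlation, and no member passed adjusted over the list alone. Without neo replicate 3 the macrophage call was lost with a median of 0.39 (adjusted p = 0.0958), and the interferon call with a median of 0.09 (adjusted p = 0.313). The interferon call was also lost without KO replicate 1 (adjusted p = 0.0826), and the mitochondrial call without KO replicate 2 (adjusted p = 0.0541).

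**Figure D3:**
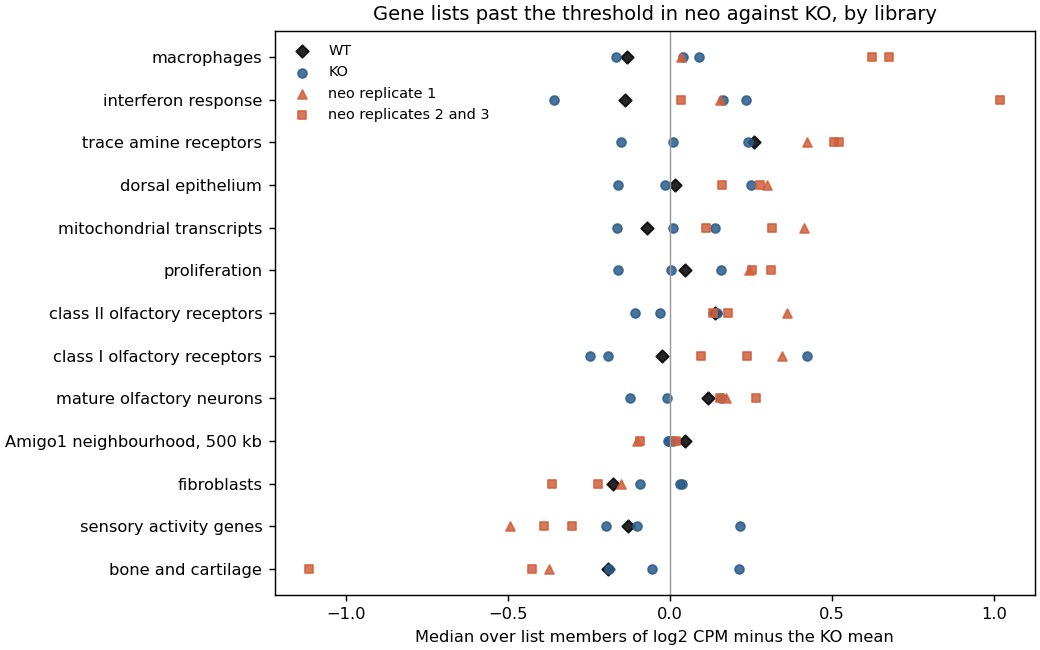
Median over list members of the log2 CPM minus the KO mean, for each library and each of the 13 lists past the threshold. WT is a diamond, KO libraries are circles, neo replicate 1 is a triangle and the other neo libraries are squares.

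The remaining lists did not pass camera, and apart from Slit3 and Plxna3 no member passed adjusted over the list alone. Neuronal and basal lists had medians of -0.01 for immature neurons (adjusted p = 0.481, camera), where Gap43 had a log2 change of -0.28, 0.09 for globose basal cells (adjusted p = 0.344) and 0.06 for horizontal basal cells (adjusted p = 0.244), where Trp63 had 0.46. Supporting and glandular lists had medians of 0.12 for sustentacular cells (adjusted p = 0.109, camera), 0.09 for Bowman glands, a list whose test pointed lower (adjusted p = 0.954), 0.15 for microvillar cells (adjusted p = 0.481), 0.08 for respiratory ciliated cells (adjusted p = 0.344) and -0.10 for ensheathing glia (adjusted p = 0.244). Blood and vessel lists had medians of -0.01 for endothelium, a list whose test pointed higher (adjusted p = 0.861, camera), 0.38 for neutrophils (adjusted p = 0.348), -0.32 for lymphocytes (adjusted p = 0.344) and 0.01 for erythroid cells, whose test pointed lower (adjusted p = 0.529). Vomeronasal neurons had 0.05 (adjusted p = 0.355, camera), type 1 and type 2 vomeronasal receptors 0.30 and 0.46 (adjusted p = 0.364 and 0.219), and olfactory bulb and brain genes -0.09 (adjusted p = 0.489). Ventral epithelium genes had -0.06 (adjusted p = 0.244, camera), where the guidance gene Slit3 had -0.63 and was the only member lower adjusted over the list alone. Axon guidance genes had -0.07 (adjusted p = 0.830, camera), where the semaphorin receptor gene Plxna3 had 0.45 and was the only member higher adjusted over the list alone. Neither Slit3 nor Plxna3 passed over all genes (adjusted p = 0.3845 and 0.3838, edgeR). Amigo family and Kv2 channel genes had -0.05 (adjusted p = 0.852, camera), receptor choice and unfolded protein genes -0.05 (adjusted p = 0.244), p53 and cell death genes -0.09 (adjusted p = 0.163), ribosomal protein genes -0.03 (adjusted p = 0.364) and sex-linked genes -0.61 (adjusted p = 0.289). Skeletal muscle genes had 4.71 (adjusted p = 0.0681, camera), with -0.98 without neo replicate 1 (adjusted p = 0.0322) and 5.68 and 5.67 without neo replicate 2 or 3 (adjusted p = 0.000680 and 4.2e-05). Leaving out 1 library also brought other lists past the threshold. Without neo replicate 1 these were horizontal basal cells, sustentacular cells, ciliated cells and neutrophils (medians 0.22, 0.21, 0.30 and 0.74, adjusted p = 0.0322, 0.00483, 0.000193 and 0.0259, camera). Without neo replicate 2 they were globose basal cells, Bowman glands, type 2 vomeronasal receptors and ribosomal proteins (medians 0.18, -0.26, 0.83 and -0.19, adjusted p = 0.0111, 3.6e-05, 0.0207 and 9.6e-05, camera). Without neo replicate 3 they were type 1 and type 2 vomeronasal receptors (medians 0.96 and 0.76, adjusted p = 0.000182 and 1.6e-06, camera). The type 2 median was -0.53 without neo replicate 1. Without KO replicate 1 they were horizontal basal, sustentacular and ciliated cells, receptor choice genes and ribosomal proteins (medians 0.26, 0.17, 0.19, -0.10 and -0.13, adjusted p = 0.00705, 0.0461, 0.0461, 0.0461 and 0.00689, camera). Without KO replicate 2 they were sustentacular cells, ensheathing glia and type 2 vomeronasal receptors (medians 0.24, -0.19 and 1.995, adjusted p = 0.0373, 0.0373 and 3.8e-06, camera).

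Neo replicate 1 stood apart from the other libraries, at 2.71 on the first dimension of a multidimensional scaling plot, which held 40.8% of the variance, against -0.84 to -0.11 for the others. It held 326 CPM of Acta1, the skeletal muscle actin gene, against at most 7.13 CPM elsewhere, and 95.9 CPM of the secretory gene Bpifb9b against 15850 to 39680 CPM elsewhere. Like WT, it was high in Xist (1145 CPM) and had 0 CPM of Ddx3y, as a female library would. Neo replicates 2 and 3 had 69.4 and 84.6 CPM of Ddx3y, so by these transcripts sex was mixed in neo and not in KO. These genes were chosen after their values were seen.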

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

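The spread without robust weighting and the receptor share without Gm42418 were chosen after the data were seen, and the other alternatives before. For genes changed between neo and KO (3), edgeR gave 40 without a count filter and 1 each with the filter of 50 counts, the replicate block and the spread without robust weighting, DESeq2 gave 95, limma on TPM gave 1 at either pseudocount, and leaving out each library gave 1 to 17. RLE factors, TMM without receptor genes, all 7 libraries and the test against a fold of 1.2 kept the same 3 genes. For gene lists (13), an estimated correlation and fry gave 0 each, the replicate block 12 and leaving out each library 10 to 18. For genes within 500 kb of Amigo1 (1), no filter gave 3 and DESeq2 4. For receptor genes (1), no filter gave 6, DESeq2 12, the filter of 50 counts 0 and the replicate block 0 in edgeR, limma on TPM 0 and 0, and leaving out each library 0 to 1. At an unadjusted p under 0.05 those counts of 0 had 131, 162, 143 and 143 receptor genes. For neo against WT (2), no filter gave 7 and leaving out each library 2 to 6. For KO against WT (1), no filter gave 2, a fit of the 2 groups alone 6 and leaving out each library 1 to 4. The ratio of receptor shares (1.16) was 0.994 per marker count, 1.199 by TPM, 1.17 without Gm42418 and 1.06 to 1.24 when leaving out each library. Neighbouring transcripts past the threshold in limma stayed at 0 in every alternative run. The median of the skeletal muscle list ran from -0.98 without neo replicate 1 to 5.68 without neo replicate 2. The shared replicate numbers did not pair the libraries, since the correlations of same-numbered KO and neo deviations were -0.10, -0.05 and 0.19, and the block left fewer degrees of freedom. Over named genes, 1251 alternative values kept direction and side of the threshold, 25 newly passed, 14 no longer passed, 17 changed sign without a call and 0 changed sign with a call. Over lists those counts were 455, 27, 43, 22 and 1, the last being skeletal muscle without neo replicate 1. The cause of these changes was not tested. Depth limits weak genes, since 0 counts allow up to 3.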

Other observations

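The WT library held transcripts that were near 0 in the others, seen only after the values were examined. Vip, which encodes vasoactive intestinal peptide, had 312 counts in WT against 0 to 11 in each mutant library. Hand2, a transcription factor gene, had 39 counts in WT and 0 in all 6 mutant libraries, and Slc18a3, the vesicular acetylcholine transporter gene, had 16 and 0. In the fit of 7 libraries Vip had a log2 difference of -7.46 between KO and WT that did not pass (adjusted p = 1, edgeR). Between KO and WT, edgeR did call Vip in the fit of WT and KO alone, and Hand2 without a count filter. Gm11942 had 44.5 to 51.4 CPM in WT and KO replicates 2 and 3, and at most 0.184 CPM in KO replicate 1 and the 3 neo libraries. Like those genes, Gm11942, Ndn and Carns1 were chosen after their values were seen. Necdin, the product of the imprinted gene Ndn, and carnosine synthase, the product of Carns1, had transcript levels that were higher in 3 of 3 neo libraries and passed in DESeq2 (adjusted p = 0.000494 for Ndn and 5.3e-05 for Carns1) but not in edgeR. Ndn was 13.95 ± 1.02 CPM in KO and 24.6 ± 2.20 CPM in neo (SD, n = 3 each, adjusted p = 0.269, edgeR), and Carns1 was 85.9 ± 3.49 and 128.0 ± 2.92 CPM (adjusted p = 0.174, edgeR).

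In the 3 patterns that follow, the counts of edgeR, list and transcript calls in other splits were set before their results were seen, and the other tests after. Splits of the 6 neo and KO libraries number 10, too few for a share under 0.05. Of these, 1 gave as many as the 3 genes called (highest other 0), 6 gave as many as the 13 lists (highest other 17), 1 gave the 1 neighbourhood gene (highest other 0), 1 gave the 1 receptor gene (highest other 0), and all 10 gave the 0 neighbouring transcripts (highest other 0). A split that put KO replicates 1 and 2 with neo replicate 1 called 0 genes by edgeR but had 1999 at an unadjusted p under 0.05, above the 1643 of the real split. DESeq2 called 168 genes in the split of KO replicate 1 with neo replicates 2 and 3, more than the 95 of the real split, which points to a structure of the libraries beside the groups.

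Gpr61 was off in the WT library and on in all mutant libraries. A cell type missing from WT is argued against, since 0 other genes with a mean of at least 5 CPM fell under a twentieth of their lowest mutant library. A wrong label on WT is argued against by Amigo1, which was 38.7 times its highest mutant library there. A strain variant linked to both altered alleles and an effect of the alleles themselves cannot be told apart, since Gpr61 was over 1 CPM in 6 of 6 mutant libraries, as either predicts. Both rest on 1 WT library.

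Cyb561d1 and Atxn7l2 were lower in neo than in KO. A difference between dates that is blind to position stays open. With Cyb561d1 and Atxn7l2 left out, DESeq2 called 2 of 30 genes within 500 kb and 91 of 18737 elsewhere (Fisher's exact p = 0.00966). Those 2 genes, Psma5 and Gm42754, had been seen before this test was set, so it cannot decide. edgeR called 0 of 28 such genes, with 4 at an unadjusted p under 0.05. The test of edgeR calls given above was set beforehand (Fisher's exact p = 0.00509), but its only call within 500 kb was Cyb561d1 itself. A cell type lost from neo stays open, since the counts met neither side of the rule set for it. A loss asked for more than 2 times as many genes lower as higher, and its absence for 2 or fewer lower. Beside Cyb561d1 and Atxn7l2, 9 genes were at least 4-fold lower without overlap and 11 as much higher. Of the lower genes 5430402E10Rik alone had a KO mean of at least 5 CPM, while 4 higher genes had such a mean in neo. A strain variant near Amigo1 that differs between the lines stays open, since Cyb561d1 in WT was 1.2 times the KO mean and WT shares its line name with KO. An effect of the cassette cannot be told apart from that variant in these libraries.

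Olfactory receptor genes lay on both sides of 0 between neo and KO. For the median receptor gene, whether a higher share of mature neurons in neo accounts for the shift stays open. The receptor median differed from the mature neuron median by 0.0734 on the log2 scale, within a spread of 0.102. That spread is over random gene sets and not over libraries, so it cannot decide. Receptor counts per mature marker count were 0.6215, 0.5131 and 0.5635 in neo replicates 1 to 3, against 0.5534 to 0.5805 in KO. For the lower receptor genes that share is argued against as the whole cause, since it would raise receptor transcripts, and DESeq2 called 9 receptor genes lower (edgeR 1) against at most 2 in 1 direction in the other splits, although at an unadjusted p under 0.05 edgeR had 50 lower and 2 other splits had 92 or more in 1 direction. Neo replicate 1 alone is argued against as the whole cause, since without it DESeq2 called 7 receptor genes lower, 6 of them among the 9. Without it edgeR had 58 lower at an unadjusted p under 0.05 against 26.3 by chance. The split of KO replicates 2 and 3 from the other 3 libraries, with 12 higher by DESeq2 and 159 lower by edgeR, points to a structure of the libraries beside the groups. Without KO replicate 2, edgeR had 25 lower at an unadjusted p under 0.05, about the number that chance gives. With no library left out, limma on TPM had 20 and 19 lower at its pseudocounts of 0.1 and 1. Its median fold over all genes was 0.097 and 0.087, against -0.002 in edgeR, so those counts come from a scale shifted upward. Whether the lower receptor genes as a set depend on KO replicate 2 therefore stays open. Across 957 adjacent pairs of receptor genes, which are not independent replicates, the rank correlation of folds was 0.277 (permutation p = 1e-04, the smallest that 10000 draws can give). It was above 0 in the other splits too, at 0.039 to 0.35, with 0.293 and 0.35 above the real split. Whether neighbouring receptor genes go together in neo against KO in particular therefore stays open.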
